A study of Mus musculus with 4 samples.

How the data were processed

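RNA-seq libraries of 4 samples of sorted thymic iNKT cells were analysed, 2 labelled Control and 2 labelled Prmt5 KO, grouped by their titles. Per the labels, cDNA was made and amplified with a SMART-seq ultra-low-input kit and sequenced on an Ion Proton, and all 4 libraries carry the same run name. The authors deposited 1 table of 46517 genes with unnormalized read counts per gene, exon, exon-exon junction and intron, each as unique and as total reads, beside RPKM values that were not used here. Per the file headers, reads were single and trimmed. The build was mm10 and edgeR was used, per the submitters' processing notes; mapper and gene annotation are not given in the sources used here. The authors also deposited a p-value and a signed fold change, a score without fixed range, per gene. Those were computed on gene reads not scaled for depth, as seen in the authors' deposited table, where Prmt5 has a fold change of 1.96; they were not used for any result here.

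For each of the 46517 genes, exon and intron reads add up to gene reads, and the authors' expression value equals total gene reads. For 15821 genes the exon length is 0 and all reads are listed as intron reads, so the intron share of all genes contains them. Coordinates in the file count starts from 0; printed starts have 1 added. Symbols were looked up in GENCODE M21, and 41980 of 46517 were found, 34820 with the same chromosome, start and end.

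Total exon reads were the input of the main test. The design had named counts but not which read column. Exon reads were chosen after the columns were seen, because introns were analysed separately, and total gene and unique exon reads were fitted in the same exploration, so the number of genes called with each was known when exon reads were kept. Genes were kept by filterByExpr (10775 genes), scaled by TMM and tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. The SE is the absolute log2 coefficient over the root of F, and none is given for genes with a group at 0 reads. The other tools were DESeq2 1.42.0 and limma 3.58.1. In 5 simulations drawn from the libraries' means and dispersions, the test on exon reads found 5.06% of genes changed 2-fold, 51.5% of those changed 4-fold, 73.3% of those changed 8-fold and 91.9% of those changed 16-fold, among 10399 genes. The simulated genes varied less in their spread than the real ones: the prior degrees of freedom were 36.9 in the simulations and 6.86 in the data, so these shares are upper values for the data. On simulated lists, camera called 5 of 5 shifted lists and 1 of 5 unchanged ones at an unadjusted p under 0.05. The simulated genes were drawn independently of each other, so this does not check camera on lists whose genes are correlated.

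The 26 pathway lists and 15 marker lists, and the rule for named genes, were fixed before the data were examined. The rule named Prmt5, Il2rg and Jak3, then, as fewer than 5 genes per direction passed, the 10 per direction with the smallest p among genes with a mean of at least 5 CPM and non-overlapping groups, and the 2 most abundant tested members of each marker list. List members were to be named up to 4 by p where the list had a member past the threshold; as none had over all genes, members past it adjusted over the list alone are named, a reading chosen after their values were seen, as were further genes of MHC class I and Klrb1c, Cd24a, Clk1, Bax, Trdc and Sox13. Lists were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over lists with at least 5 tested members. An estimated correlation and fry were alternatives. With the correlation estimated, camera rests on the 2 residual degrees of freedom of the fit and has little power. A call lost there need not come from correlation between genes. The marker lists, fixed at the same time, were to be reported as levels; their camera tests, adjusted as a separate family, were added after the data were seen. The value of 1 marker gene is not reported here. The intron test compared unique intron and exon reads in edgeR with library as a block, for genes with at least 20 unique exon reads in every library and at least 10 unique intron reads in total. Intron density used introns over 1000 bases in all per gene, and silent genes had 0 exon reads and fewer than 200 unique intron reads. Genes with an exon length of 0 were not left out of the silent genes. For them the whole gene counts as intron, so the silent genes can include transcribed ones.

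Depth was 4600799 to 13240293 exon reads per library, and 1 read was worth 0.0678 to 0.235 CPM. Prmt5 KO 1 was the deepest library. Where a group had 0 reads, 3 counts over the group served as floor, which covers counting error only. PCR reads without molecular identifiers are not independent molecules. Alternatives were other scalings, tools, filters, thresholds and read columns, the replicate number as a block, and each library left out. The libraries of a group differed by more than counting noise, with a chi-square over genes at 36.1 times its degrees of freedom for Control and 70.3 for Prmt5 KO, so neither pair was treated as 1 library deposited again. This does not tell separate mice from technical repeats of amplified RNA. Each per-library column of the table carries a library name given in the labels.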

Results

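RNA was sequenced from thymic invariant natural killer T (iNKT) cells of C57BL/6J mice. These are T cells with a semi-invariant receptor that recognises lipids presented by CD1d. Per the labels, cells were sorted at stage 1, a gate negative for CD24, NK1.1 and T-bet. PRMT5 is an enzyme that places symmetric dimethyl groups on arginine residues, among them those of the Sm proteins of the spliceosome. The comparison asked how deletion of Prmt5 with Cd4-Cre, which acts in developing T cells, changes the transcripts of these cells. There were 2 libraries labelled Control and 2 labelled Prmt5 KO. The labels give the Control genotype as either floxed without Cre or heterozygous floxed with Cre, without saying which library had which. Nothing in the labels says that the libraries came from separate mice, so p-values measure the spread between libraries, which may be technical. Reads on annotated exons numbered 5571860 and 4600799 in Control 1 and 2, and 13240293 and 5355378 in Prmt5 KO 1 and 2. Levels below are exon CPM scaled by TMM, as mean ± SD of 2 libraries per group, and log2 fold changes are Prmt5 KO minus Control.

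In exon reads the targeted gene did not separate the groups. Prmt5 (chromosome 14, 54507187 to 54517525 on mm10, a protein-coding gene on the minus strand) stood at 99.0 ± 1.05 CPM in Control and 103 ± 22.8 in the libraries labelled Prmt5 KO (SD, n = 2 each). Exon reads of Prmt5 numbered 555 and 425 in Control and 1279 and 604 in the libraries labelled Prmt5 KO. Its log2 fold change was 0.05 ± 0.32 (SE), with an adjusted p of 0.992 in edgeR's quasi-likelihood test. Without Prmt5 KO 2 the sign turned, at -0.19. The table holds no reads per exon and the labels do not name the floxed part, so reads of the remaining transcript are counted with the rest. The gene-level count therefore does not check the labels, and groups are named here as labelled.

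H2-Q7, a non-classical MHC class I gene of the Qa-2 antigen, fell in the libraries labelled Prmt5 KO. It went from 186 ± 7.40 CPM in Control to 3.88 ± 1.31 (SD, n = 2 each), a 46.0-fold lower fitted level (log2 fold change -5.52 ± 0.42 SE, adjusted p = 0.00415). The gene lies on chromosome 17, from 35439155 to 35443773 on mm10. It is part of a family of near-identical copies, so its level is uncertain. With unique exon reads only it remained past the threshold, at a log2 fold change of -5.56. Fitted on group alone, edgeR's quasi-likelihood test passed only H2-Q7 of 10775 genes at an adjusted p under 0.05, with 0 higher and 1 lower. The fit with the replicate number as a block called many more and is given below. An unadjusted p under 0.05 was reached by 924 genes, where chance alone gives about 539. Other tools on the same counts called more. DESeq2 called 93 genes higher and 78 lower, the edgeR exact test 111 higher and 81 lower, and limma-voom 1 higher and 12 lower. Exon reads were chosen after several read columns had been fitted. The total gene reads, which the authors' table repeats as its expression value, gave 5 higher and 9 lower.

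Below the threshold, several genes had lower levels in the libraries labelled Prmt5 KO, each in both libraries. Jak3, the kinase that signals below the common gamma chain of cytokine receptors, was at 221 ± 4.47 CPM in Control and 40.2 ± 10.3 in Prmt5 KO (log2 fold change -2.46 ± 0.34 SE, adjusted p = 0.0561). Cxcr3, a chemokine receptor, was at 107 ± 11.9 and 7.54 ± 3.71 CPM. Itgae, the integrin chain CD103, was at 290.5 ± 41.0 and 44.1 ± 8.66 CPM. Vdr, the vitamin D receptor, was at 164 ± 6.16 and 24.0 ± 4.45 CPM, and Hcst, the adaptor DAP10, at 127 ± 9.35 and 20.3 ± 1.07 CPM. Bcl2a1b, a survival gene with near-identical neighbours and therefore an uncertain count, was at 154 ± 30.2 and 24.8 ± 0.85 CPM. The log2 fold changes of Fam173a and Pcsk1 were -3.08 and -3.91, and these 7 genes beside Jak3 all had an adjusted p of 0.0561. Blk, a Src-family kinase, had 645 and 261 exon reads in Control and 35 and 0 in Prmt5 KO (adjusted p = 0.0880). Il2rg, which encodes the common gamma chain, was at 1471 ± 383 and 734 ± 161 CPM, with an adjusted p of 0.496. Between 13.96% and 28.4% of its exon reads were unique. It overlaps the gene model Gm20489 on chromosome X, and with unique exon reads alone its log2 fold change was -0.40, so its level is uncertain.

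**Figure D1:**
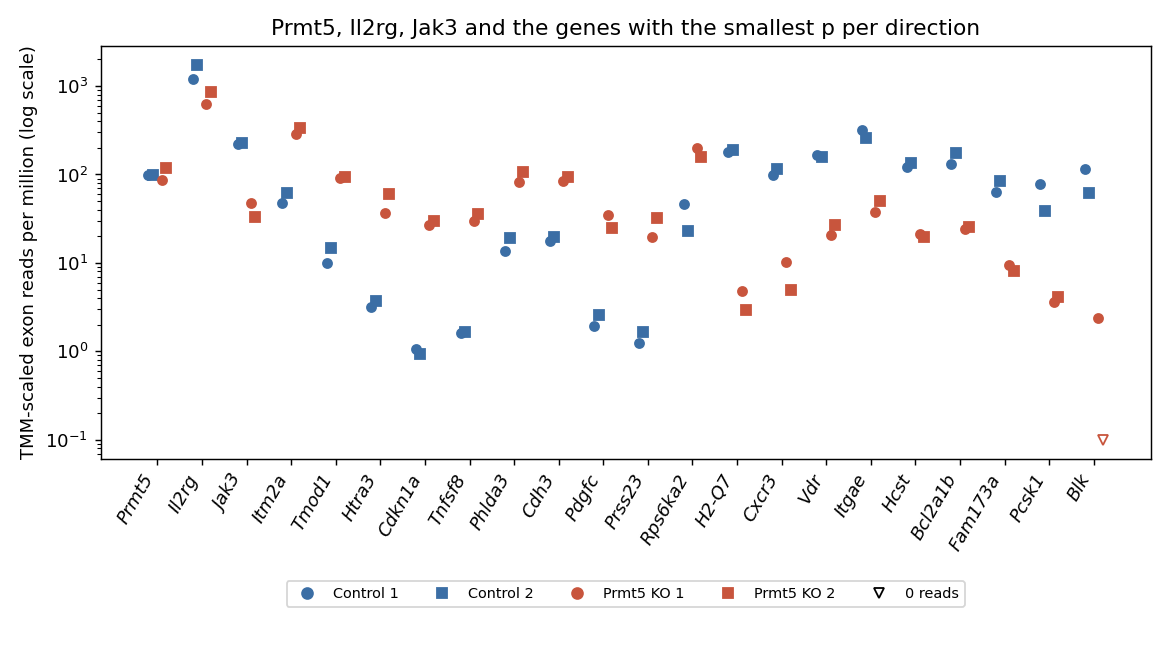
TMM-scaled exon CPM on a log axis for Prmt5, Il2rg, Jak3 and the 10 genes per direction with the smallest p, with each point a library (blue, Control; red, Prmt5 KO; circle, replicate 1; square, replicate 2; open triangle, 0 reads, drawn at an arbitrary low position). Prmt5 overlaps between the groups, while H2-Q7 stands at a mean of 186 in Control and 3.88 in Prmt5 KO.

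Other genes had higher levels, also below the threshold. Cdkn1a, the cell-cycle inhibitor p21, was at 1.00 ± 0.0873 CPM in Control and 28.5 ± 2.32 in Prmt5 KO (log2 fold change 4.80 ± 0.69 SE, adjusted p = 0.0561). Itm2a was at 55.1 ± 10.1 and 311 ± 36.2 CPM, Tmod1 at 12.4 ± 3.45 and 92.5 ± 0.393 CPM, and Tnfsf8, the CD30 ligand, at 1.62 ± 0.0350 and 32.6 ± 4.35 CPM. Htra3 was at 3.47 ± 0.402 and 48.3 ± 16.3 CPM. These 4 genes also had an adjusted p of 0.0561. Phlda3 and Cdh3 had log2 fold changes of 2.52 and 2.25, with adjusted p of 0.0880 and 0.0972. Pdgfc, Prss23 and Rps6ka2 had log2 fold changes of 3.71, 4.16 and 2.35, each with an adjusted p of 0.104. Of the 20 genes with an adjusted p under 0.10, 7 were higher and 13 lower. Of these 20, 19 were also called by DESeq2 and 20 by the edgeR exact test at 0.05. The groups' values did not overlap for 2210 genes upward and 2047 downward, and chance gives this for 33.3% of genes with 2 against 2.

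The p53 target list was shifted upward. Its 25 tested members had a median log2 fold change of 1.16, 23 of them positive, and 10 were higher when adjusted over the list alone, against 0 over all genes tested. Among them were Cdkn1a, Phlda3, Bbc3 (11.6 ± 4.42 and 47.2 ± 6.54 CPM), which encodes the pro-apoptotic PUMA, and Psrc1 (log2 fold change 3.18). Camera with its preset correlation gave an adjusted p of 8.91e-09, and with an estimated correlation the adjusted p = 0.197. The estimated correlation was -0.012, below the preset 0.01, so it does not account for the higher p. That test rests on 2 residual degrees of freedom. Without Prmt5 KO 1 the median was 0.66, with 10 members higher and 1 lower adjusted over the list alone, and without Control 1 and Control 2 the number higher adjusted over the list alone was 5 and 3. In the BCL2 family and caspase list, 3 of 20 tested members were higher and 2 lower, adjusted over the list alone. Bcl2, which protects cells from apoptosis, was at 37.3 ± 15.4 and 151 ± 30.9 CPM. Bcl2a1b and Bcl2a1d (log2 fold changes -2.63 and -1.43), paralogs that also protect cells, went the other way. Without Control 2 or Prmt5 KO 1, 1 member of that list was higher and 1 lower, and without either of the others 2 and 2. The list's median was 0.06 and camera gave an adjusted p of 0.837. With 1 library left out the median ranged from -0.10 (without Control 2) to 0.30 (without Control 1).

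Genes of the gamma chain and its signalling showed no shared direction in the list test. Of 14 tested members, Jak3 alone was lower adjusted over the list alone, and the median log2 fold change was 0.19 (camera adjusted p = 0.939). The mean was -0.10 and of opposite sign, but it was 0.02 without Control 2 and -0.38 without Prmt5 KO 1. Mixed fry, which asks for change in either direction, gave an adjusted p of 0.00487, and the call was lost with each library left out in turn (0.0603 to 0.174). In the STAT5 and cytokine response list, 1 of 17 tested members was higher adjusted over the list alone, namely Bcl2, and camera gave an adjusted p of 0.593. That count was 0 without Control 1 and 2 without Control 2 or Prmt5 KO 1, the last with 1 lower.

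Genes of the NKT17 and NKT1 subsets had lower levels. NKT17 genes had a median log2 fold change of -3.13 over 13 tested members, 12 of them negative, and 8 were lower adjusted over the list alone (camera adjusted p = 8.91e-09; adjusted p = 0.197 with an estimated correlation). Examples were Blk, Aqp3 (45.6 ± 30.4 and 2.18 ± 1.42 CPM), Maf (44.4 ± 12.3 and 10.5 ± 3.49 CPM) and Il23r, with 0 reads in both libraries labelled Prmt5 KO and a level at least 42.7-fold lower against a floor of 3 counts over the group. NKT1 genes had a median of -1.63 over 16 tested members, 13 of them negative, and 4 were lower adjusted over the list alone (camera adjusted p = 4.37e-05; adjusted p = 0.262 with an estimated correlation). These were Cxcr3, Ly6c2 (log2 fold change -2.60), Klrk1, at 0 reads in both libraries labelled Prmt5 KO and at least 59.4-fold lower, and Tbx21, which encodes T-bet (85.8 ± 30.1 and 9.56 ± 5.45 CPM). T-bet protein was used in the sort, as was NK1.1, whose gene Klrb1c was at 36.8 and 13.1 CPM in Control and 2.91 and 13.8 CPM in Prmt5 KO, so that the groups overlapped (adjusted p = 0.632). The medians were unchanged with the genes at 0 placed at their bound. Without Control 1 the NKT17 and NKT1 medians were -1.71 and -0.64, with 4 and 2 members lower adjusted over the list alone. The NKT1 median was -0.92 without Prmt5 KO 1, where 2 members were higher and 5 lower adjusted over the list alone, and 5 NKT17 members were lower adjusted over the list alone without Control 2. The NKT2 list had a median of 0.22 (camera adjusted p = 0.594), which was 0.0059 without Prmt5 KO 2 and 0.34 without Prmt5 KO 1. Of its 16 tested members 1, Lef1, was higher adjusted over the list alone. None was higher without Control 1 or Control 2, and 1 was also lower without Prmt5 KO 2.

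The list of iNKT lineage development had a median log2 fold change of 0.53 over 26 tested members. Adjusted over the list alone, 6 were higher and 1 lower (camera adjusted p = 0.00184; adjusted p = 0.306 with an estimated correlation). Adjusted over the list alone, 2, 0 and 3 were higher without Control 1, Control 2 and Prmt5 KO 1. Lef1, a transcription factor of early T cells, was at 503 ± 24.2 and 1572 ± 189 CPM. Tox2 was at 37.5 ± 6.27 and 149 ± 39.0 CPM, and Egr2, induced by T cell receptor signals, at 50.9 ± 16.9 and 147 ± 33.6 CPM. Runx3, which goes with effector differentiation, was the lower member, at 52.5 ± 7.58 and 9.48 ± 2.19 CPM. Cd24a, whose protein was excluded by the sort, had 0 reads in both Control libraries and was at 5.56 and 2.56 CPM in Prmt5 KO 1 and 2, at least 15.8-fold higher. In the homing and adhesion list, 3 of 18 tested members were lower adjusted over the list alone (Cxcr3, Itgae and Itgb7, the last with a log2 fold change of -1.44) and 1, Cd69, was higher (camera adjusted p = 0.310). Without Control 1 or Control 2, 0 were higher, with 4 and 2 lower, and without Prmt5 KO 2 the counts were 2 higher and 4 lower.

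Interferon-stimulated genes were lower as a list. The median log2 fold change was -0.92 over 27 tested members, 26 of them negative, and 6 were lower adjusted over the list alone (camera adjusted p = 1.63e-09; adjusted p = 0.197 with an estimated correlation). Without Control 2, 3 were lower adjusted over the list alone. Ifit1 was at 96.3 ± 3.65 and 25.9 ± 2.10 CPM, Ifit3 at 84.5 ± 1.97 and 18.9 ± 7.59 CPM, and Ifi27l2a at 614 ± 211 and 142 ± 84.9 CPM. Ifit3b, a near copy of Ifit3, had a log2 fold change of -3.37 and is uncertain for that reason.

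**Figure D2:**
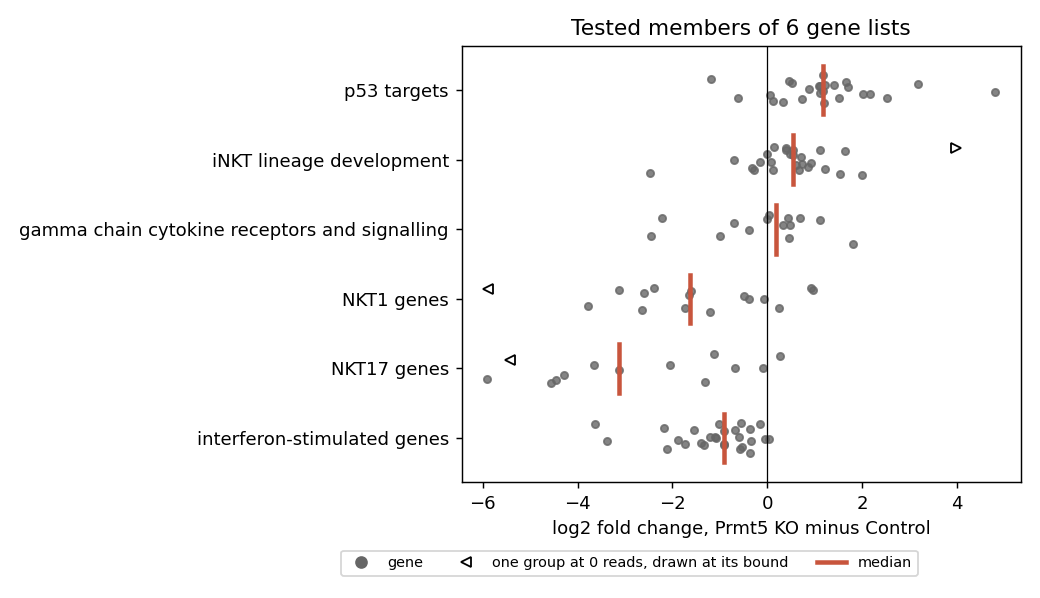
Log2 fold changes, Prmt5 KO minus Control, of the tested members of 6 gene lists, with each grey point a gene, open triangles genes with a group at 0 reads drawn at their bound, and red bars the medians. The p53 targets have a median of 1.16, and the NKT17 genes a median of -3.13.

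Camera with its preset correlation also called 6 other lists, with smaller medians, and each was lost with an estimated correlation (adjusted p of 0.657 to 0.833). G2/M phase genes had a median of -0.47 (adjusted p = 0.000549; Hmgb2 was at 1141 ± 142 and 715 ± 41.4 CPM), S phase genes -0.36 (0.0154), replication-dependent histones -0.42 (0.0164), ribosomal proteins -0.33 (0.00738) and oxidative phosphorylation -0.23 (0.0379). Glycolysis and glucose uptake had a median of 0.40 (adjusted p = 0.00738), with Eno1, a glycolytic enzyme, at 2832 ± 321 and 4461 ± 1581 CPM. Adjusted over the list alone, 0 members of these 6 lists passed. The direction of the ribosomal proteins depended on 1 library, however. Of 49 tested, 48 had a negative log2 fold change without Prmt5 KO 2, and 10 without Prmt5 KO 1. Without Prmt5 KO 1, the medians of ribosomal proteins and oxidative phosphorylation turned to 0.10 and 0.02, and without Control 2 that of histones turned to 0.01. Without Prmt5 KO 2 the calls of G2/M phase, S phase and glycolysis were lost, at medians of -0.16, -0.20 and 0.15 (adjusted p of 0.125, 0.115 and 0.222). Without Control 2 those of S phase (median -0.13), ribosomal proteins (-0.05), oxidative phosphorylation (-0.02) and glycolysis (0.40) were lost, as was that of histones without Prmt5 KO 1 (-0.11). The G2/M median was -0.29 without Control 1 and -0.71 without Prmt5 KO 1, and without Prmt5 KO 2 those of ribosomal proteins, oxidative phosphorylation and histones were -1.02, -0.58 and -0.85. No list test with a preset correlation passed for the Sm and LSm spliceosome proteins (adjusted p = 0.0734), ribosome biogenesis (0.0734), splicing regulators (0.192), the unfolded protein response (0.250), DNA repair (0.255), cytokines and chemokines (0.314), arginine methyltransferases (0.794), cholesterol synthesis (0.837) or T cell receptor signalling (0.912). Leaving out 1 library brought calls with the preset correlation. These were the Sm and LSm proteins without Prmt5 KO 2 (median -0.61) and without Control 1 (-0.58). Splicing regulators were called without Prmt5 KO 2 (0.35) and DNA repair without Prmt5 KO 1 (-0.73). None was called with an estimated correlation, but such a fit leaves too few residual degrees of freedom for that test to pass in practice. Prmt1, the most abundant tested methyltransferase gene, had a log2 fold change of -0.40, and Lck one of -0.15. In the ATF4 list (camera adjusted p = 0.253), Phgdh was lower and Sesn2, also a p53 target, higher adjusted over the list alone (log2 fold changes -1.53 and 2.17). Without Control 2 or Prmt5 KO 1 no member of that list passed, and none was lower without Control 1.

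Markers of other cells were mostly low. The B cell gene Ms4a1 had 0 reads in every library, and Ighm, the B cell marker that was tested, was at 136 ± 25.3 and 45.5 ± 6.22 CPM. Of the NK cell list, Fcer1g was at 21.5 ± 12.1 and 95.1 ± 58.4 CPM and Klra3 had a log2 fold change of -0.53; Cpa3, a mast cell gene also seen in thymic precursors, had 0 reads in Control and was at least 17.0-fold higher. Ighm and Cpa3 were the tested members of their lists, with unadjusted p of 0.00115 and 0.00684 in edgeR and adjusted p of 0.172 and 0.335 over all genes. Adjusted over the list alone, 2 of 4 tested NK cell genes were higher. Tcrg-C2 and Tcrg-C4 had log2 fold changes of -0.72 and -0.41, and the gamma-delta T cell list was lower by camera (adjusted p = 0.0210; adjusted p = 0.570 with an estimated correlation), with 2 of 7 tested members lower adjusted over the list alone and 2 listed genes shared with the NKT17 list. Bst2 and Cst3 of the myeloid list had log2 fold changes of -1.08 and -0.37, Themis and Rmnd5a of the double-positive thymocyte list 1.12 and 0.24, and Ccr7 and Cd4 of the conventional T cell list 0.51 and 0.30. Pecam1 was at 0.77, Ly75 and Ccl25 of the epithelial list at 1.15 and -1.38, and Xbp1 and Sdc1 of the plasma cell list at -0.26 and -0.68. Camera gave an adjusted p of 0.444 for the myeloid list, 0.467 for double-positive thymocytes (2 higher and 1 lower of 8 adjusted over the list alone), 0.305 for conventional T cells, 0.759 for handling genes and 0.866 for mitochondrial transcripts. No erythroid gene passed the filter on low counts. Hspa8 and Dusp2 of the handling list had log2 fold changes of -0.58 and 0.21, and mt-Co3 and mt-Co1 -0.01 and 0.05. Malat1 and Gas5 of the list named nuclear-retained RNAs were at 1.73 and -0.33, and the Y-linked Ddx3y and Eif2s3y at 0.62 and -0.90. Adjusted over the list alone, 2 of 4 tested members of the list named nuclear-retained RNAs were higher, Malat1 and Snhg3. Nuclear retention of Gas5 and Snhg3 was not shown here. Pecam1, the tested member of the fibroblast and endothelium list, had an adjusted p of 0.500 over all genes. Leaving out 1 library turned the signs of Klra3, Cst3, Xbp1, Sdc1, Ddx3y, mt-Co3 and mt-Co1, and the last 2 also turned under other settings.

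Reads on introns made up a larger share in the libraries labelled Prmt5 KO. Of unique gene reads, 4.25% and 5.86% lay in introns in Control 1 and 2, and 8.11% and 7.11% in Prmt5 KO 1 and 2, giving 5.06% ± 1.14 and 7.61% ± 0.707 (SD, n = 2 each). An exact two-sided permutation test gave p = 0.333, the smallest that 2 against 2 allows, so the share cannot pass a threshold. Among genes with at least 20 unique exon reads in every library the means were 2.98% and 5.19%. Per gene, edgeR's quasi-likelihood test of the interaction of read kind and group called 0 of 7400 genes, with 503 at an unadjusted p under 0.05 against about 370 by chance, and 502 of those 503 were higher. The median change in intron-to-exon ratio was 1.09 (log2), positive in 6072 genes. With intron reads scaled by their own totals, the median was 0.18, positive in 4125 genes, and 238 genes had an unadjusted p under 0.05, 199 of them higher. In simulated data with an assumed dispersion this test found 6.4% of genes whose ratio was changed 8-fold. Jak3, whose exon level was lower, had 2.21% and 1.91% of its unique reads in introns in Control and 11.99% and 12.9% in Prmt5 KO. In that edgeR test its unadjusted p was 0.0346 and its adjusted p 0.717, and the unadjusted p was 0.0804 with the separate scaling. Its unique intron reads numbered 27 and 18 in Control, 92 in the deepest library, Prmt5 KO 1, and 24 in Prmt5 KO 2. Its unique exon reads numbered 1197 and 924 in Control and 675 and 162 in Prmt5 KO, and this fall by itself raises the intron share. Of the p53 list, 17 members were tested and 13 had a positive change; of the gamma chain list, 10 were tested and 9 had one, and 0 of either passed over the list alone. With the separate scaling only 6 and 6 were positive. The targeted gene Prmt5 had 0 and 1 unique intron reads in Control and 11 and 35 in the libraries labelled Prmt5 KO. Il2rg had 0 unique intron reads in every library and so was not among the tested genes. Its total intron reads numbered 21 and 26 in Control and 372 and 63 in Prmt5 KO. They made up 0.31% and 0.35% of its total reads in Control, and 3.91% and 1.44% in Prmt5 KO. As none of them was unique, their origin is uncertain. Malat1, an RNA kept in the nucleus, was at 289 ± 204 and 958 ± 495 CPM (adjusted p = 0.415 in the main edgeR test). In the list named nuclear-retained RNAs, 2 of 4 tested members were higher adjusted over the list alone, Malat1 and Snhg3. Nuclear retention of Snhg3 was not shown here, so that count is no measure of nuclear RNA.

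**Figure D3:**
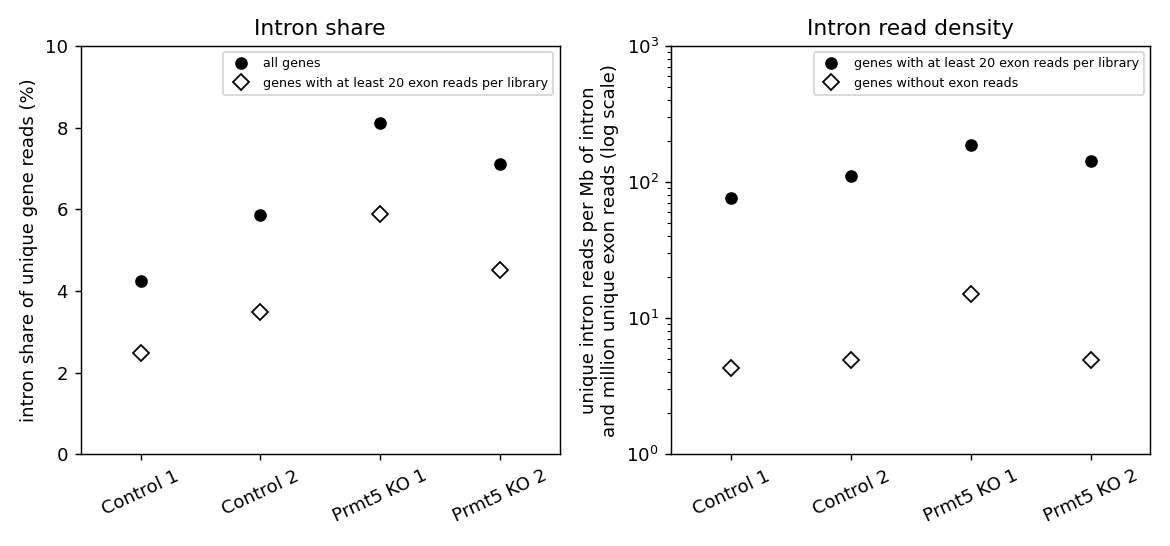
Left, share of unique gene reads in introns per library, for all genes (filled) and genes with at least 20 exon reads per library (open); right, unique intron reads scaled by intron length and by unique exon reads, on a log axis, for genes with at least 20 exon reads (filled) and genes without exon reads (open). The intron share of all genes lies at 4.25% and 5.86% in Control and at 8.11% and 7.11% in Prmt5 KO, and genes without exon reads stand at 14.9 in Prmt5 KO 1 and 4.93 in Prmt5 KO 2.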

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

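Alternatives were planned before the data were examined, except the other read columns and those of the intron ratio test, chosen after. H2-Q7 passed under all 17 alternatives, but the number of genes called did not hold. Against 1 gene (0 higher, 1 lower), DESeq2 called 171 (93 higher, 78 lower), the edgeR exact test 192 (111 and 81), limma-voom 13 (1 and 12), no low-count filter 215 (110 and 105), an adjusted p under 0.10 gave 20 (7 and 13), total gene reads 14 (5 and 9) and unique gene reads 3 (0 and 3). The replicate numbers are not stated to pair the libraries. With the replicate number as a block, 362 were called (180 and 182), among them the 20 with an adjusted p under 0.10 without it. The same-numbered libraries' deviations correlated across genes at 0.177. Some levels followed the replicate number. For example, mt-Co3 was at 1852 and 3885 CPM in Control 1 and 2, and 1753 and 3939 in Prmt5 KO 1 and 2. Fos was at 327 and 111 CPM, and 221 and 46.5, in the same order. Pearson correlations between libraries were mixed, at 0.907 for Control 1 with Prmt5 KO 1 and 0.831 for Control 2 with Prmt5 KO 2. Within groups they were 0.903 for Control and 0.882 for Prmt5 KO. These values do not settle whether the libraries were paired. The prior degrees of freedom, which set how far the test trusts each gene's own spread, were 6.86 in the fit with 1 call and 40.3 with the block. Leaving out a library, with the lone library assumed to vary like the others, gave 1 to 37 genes (0 to 13 higher, 1 to 24 lower), with 37 without Prmt5 KO 2, 9 without Prmt5 KO 1 and 4 without Control 2. The Prmt5 log2 fold change ranged from -0.19 to 0.27 without a library.

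Camera called 11 lists, and 0 with an estimated correlation. That correlation was -0.037, 0.00038 and -0.012 for the interferon, NKT17 and p53 lists, not above the preset 0.01. It is therefore not why those 3 calls were lost. With the correlation estimated, the test rests on 2 residual degrees of freedom and can hardly pass. Directional fry called 0. Mixed fry, which asks for change in either direction, called 10. Among them were 5 of the 11, beside the gamma chain, homing, NKT2, BCL2 family and unfolded protein response lists. Without a library 6 to 12 were called, 6 without Control 2. Leaving out a library moved the medians of ribosomal proteins from -1.02 to 0.10, oxidative phosphorylation from -0.58 to 0.018 and histones from -0.85 to 0.0057. Log2 fold changes without a library ranged from -1.36 to 0.23 for Cst3, -1.24 to 1.05 for Klra3, -0.50 to 0.060 for Xbp1, -1.27 to 0.36 for Sdc1, -0.70 to 0.61 for mt-Co3, -0.80 to 0.74 for mt-Co1, -0.49 to 1.24 for Ddx3y, -0.13 to 0.72 for Psmb8 and -0.25 to 0.064 for Tap1. The log2 fold change of mt-Co3 turned to 0.056 with library totals, 0.025 with limma-voom and 0.0040 without a filter, and that of mt-Co1 to -0.00065 with total gene reads and -0.035 with unique gene reads; Psmb8 turned to -0.16 with unique exon reads and -0.22 with unique gene reads. Without a filter the median log2 fold change of all genes was 0.15. The intron share difference of 2.55 percentage points ranged from 1.75 to 3.36 without a library, and the intron ratio test called 0 genes under every alternative but 1, with 1 gene without Prmt5 KO 2. The causes of these changes were not tested.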

Other observations

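Other MHC class I genes were lower beside H2-Q7, a group gathered after the values were seen. H2-K1 had a log2 fold change of -2.08 ± 0.35 SE, H2-D1 one of -1.93, H2-T23 -1.32, H2-T22 -1.21 and B2m, the light chain, -1.21. H2-Q6, a near copy of H2-Q7, was at 48.6 ± 15.6 CPM in Control and 0.915 ± 1.29 in Prmt5 KO. Of the peptide supply, Psmb9 was lower too, at -1.21, while Tap1, Tap2 and Psmb8 had log2 fold changes of -0.09, 0.26 and 0.35. The sign of Tap1 turned without either Control 1 or Prmt5 KO 1, and that of Psmb8 without Prmt5 KO 2 and with unique reads. None of these passed the threshold over all genes. The level of H2-Q6 is uncertain for its similarity to H2-Q7, and in Control 2 only 10625 of 30951 exon reads of B2m and 1278 of 2469 of H2-T23 were unique. Clk1, a kinase of splicing factors, was at 33.3 ± 3.55 and 93.9 ± 29.8 CPM, and Bax, a p53 target, at 143 ± 12.9 and 304 ± 18.7 CPM. With each library thinned to the same 3886087 unique exon reads, which leaves its intron share as it was, 173 genes had at least 5 unique intron reads in each library labelled Prmt5 KO and at most 1 over both Control libraries, and 0 had the opposite. The other pairs that held Prmt5 KO 1 gave 96 and 110 genes, and those without it 3 and 1.

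The tests below were chosen after the values had been seen, except those of background density and of reads with several positions.

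The first pattern is the higher intron share. Genomic DNA spread evenly over introns is argued against as the whole cause in these libraries. Silent genes matched 7.36% of the excess density (95% bootstrap interval 6.80 to 7.96), 10.95% in Prmt5 KO 1 and 0.627% in Prmt5 KO 2. Bootstrap intervals here resampled genes with the libraries held fixed, so they do not measure the spread between libraries. The silent genes can include transcribed ones of exon length 0, so the matched shares are approximate. The test planned for background, the KO over Control factor in expressed relative to silent genes, gave 0.825 (0.765 to 0.895) and decides nothing, because background adds reads per base and does not multiply them. Reads with several positions and ribosomal RNA are argued against by unique reads, whose median log2 ratio was 1.02 higher (0.980 to 1.06). More nuclear or unspliced RNA at 1 factor in every gene, which the log2 fold change of 1.73 in the nuclear-retained Malat1 (adjusted p = 0.415) would go with, cannot be told apart from a change in splicing: after separate scaling 238 genes had an unadjusted p under 0.05, where chance gives about 370, but the test has little power, and an effect of Prmt5 loss stays open.

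The second pattern is the higher level of p53 targets. A handling response is argued against by immediate-early and heat-shock genes without Btg2. Their median log2 fold change was -0.23 (SD 0.682 over 18 members), against 1.16 for the p53 list. This SD is over genes and does not measure the spread between libraries. That spread can be large, as for Fos, at 327 and 111 CPM in Control and 221 and 46.5 in Prmt5 KO. The depth of Prmt5 KO 1 alone is argued against by the p53 list's median of 0.66 without that library, with 21 of 25 members positive. The list was then still called with the preset correlation and not with an estimated one. The latter test has too few residual degrees of freedom there to pass in practice. Loss of Prmt5 and the presence of Cre stay open, untested, since the labels do not say which Control library carried Cre.

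The third pattern is the lower level of NKT17 and NKT1 genes. Gamma-delta T cells in the Control libraries, which the iNKT sort should remove, cannot be told apart from it: Trdc was at a mean of 1.26 CPM in Control and 2.60 in Prmt5 KO, but from 1 and 10 Control reads. Of that list's 7 tested members 6 were negative, among them Sox13 at 80.5 ± 39.4 and 18.0 ± 4.79 CPM. Fewer cells of differentiated subsets within the gate cannot be told apart from lower transcription in the same cells. Tbx21 had a log2 fold change of -3.13, as either would give. The SD of 1.82 over the 27 members with an SE was above their mean SE of 0.810. That spread decides neither, since NKT17 and NKT1 cells lost by different amounts would also give it.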
